A study of Mus musculus with 9 samples.

How the data were processed

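Total RNA of flow-sorted Lbx1-EGFP positive forelimb cells was measured on Affymetrix Mouse Genome 430 2.0 arrays. Per the labels' protocols, forelimbs of genotyped embryos were digested with collagenase, passed through a 30 um filter and sorted for green fluorescence, and 200 ng of RNA was labelled with biotin. The table used here holds 45101 probe sets on 9 arrays, 3 each of WT, HET and MUT, as the labels name the genotypes. No further per-sample columns were present.

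The submitters' processing notes name RMA, with the version not given in the sources used here. The values show 2 scales. The deposited values of replicates 1 and 2 of each genotype are linear signal intensity values, with a mean without the lowest and highest 2% of 500 on each array, a form that RMA does not give. The deposited values of replicate 3 of each genotype are log2 values with nearly equal quantiles on the 3 arrays. How the linear columns were summarised is not given in the sources used here. No column was identical to another.

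The design written before the data were examined assumed a single log2 scale and no block. Because the scales differ by replicate number, linear signals were taken to log2(signal + 16), log2 values were left as they were, and the replicate number entered the model as a block. This departure was decided before any test was run. Each scale holds 1 array of each genotype per number, so genotype and scale are balanced. On the linear arrays differences are on the log2(signal + 16) scale, which understates those of dim genes. Arrays with the same number deviated together from their group means, with r across genes of 0.364 to 0.382 for number 1, 0.362 to 0.427 for number 2 and 0.725 to 0.798 for number 3. The numbers were treated as pairing the arrays. Each group mean holds arrays of both scales, so the difference between the scales enters these r values. Among the linear arrays alone r was 0.0850 to 0.136. The pairing of numbers 1 and 2 is therefore an assumption, which the labels do not state. The log2 scale coincides with number 3, so the scale, a batch and a day cannot be told apart here.

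Probe sets were named from the platform annotation, with symbols updated through the gene identifiers of a RefSeq table (assembly GRCm38.p6, used for names and neighbours only, since the sources used here name no build). Of the probe sets, 34945 had 1 gene symbol, 932 several and 9160 none, and 64 control probe sets were left out. For 204 probe sets the older symbol was kept. A gene was represented by its probe set with the highest mean over 9 arrays, which gave 18193 genes, 9010 of them with further probe sets. 0 probe sets carried the symbol Pitx2, so the targeted gene's transcript is not reported here by name.

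All 9 arrays entered 1 linear model with genotype and number (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 4 residual and 1.77 prior degrees of freedom). Contrasts were MUT minus WT, HET minus WT, MUT minus HET and HET minus the midpoint of WT and MUT, with an F test for any genotype difference. Adjusted p-values are Benjamini-Hochberg values over all genes, with a threshold of 0.05. The median 95% confidence half-width of a pairwise difference was 0.37 log2, 0.26 in the brighter and 0.66 in the dimmer part of the genes when parted at the median level. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

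Gene lists were fixed before the data were examined and were tested with camera (preset correlation of 0.01), camera with an estimated correlation, and fry, over 29 lists. They were limb muscle progenitor regulators, myogenic differentiation regulators, sarcomere and contraction, actin cytoskeleton and motility, adhesion receptors, limb mesenchyme, cartilage, neurons and dorsal spinal interneurons, Schwann cell precursors, endothelium, pericytes, erythroid cells, macrophages, epidermis, S phase, G2 and M phase, the Wnt, Notch, BMP and FGF pathways, Hox genes, immediate early genes, p53 targets, hypoxia and glycolysis, sex-linked genes, interferon response, liver, ribosomal proteins and genes within 10 Mb of Pitx2. Of 899 genes wanted, 844 were measured. A count adjusted over the list alone uses only the p-values of its members. With an estimated correlation camera uses the 4 residual degrees of freedom, and with a preset one a number near that of the genes. The test with an estimated correlation is therefore stricter at the same correlation.

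The genes named were fixed by rule. Where fewer than 10 genes passed, the 10 with the smallest p were named, as not passing. Lbx1, Pax3, Met, Myf5, Myod1 and Myog were always named, with up to 4 members for each list described, in order of p. The 5 smallest p were named for the midpoint and F tests. The 2 unnamed probe sets, the further neuron genes given as levels and the sex-linked genes were chosen outside this rule.

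The scripts were tested on simulated data with the real arrays' means and gene-wise spreads. For MUT minus WT over 18193 genes, with 5 runs of 200 changed genes, 12.4% of changes of 0.5 log2 were recovered, 50% of 1, 77.2% of 2 and 88% of 3, with 8 false calls among 577. These shares hold for that number of changed genes and for independent normal errors. With fewer changed genes the Benjamini-Hochberg threshold is stricter, and that case was not simulated. A list shifted by 0.3 log2 was called by camera in 20 of 20 runs of simulated genes that were independent of each other, with 1 call of an unshifted list.

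Alternatives were trended and robust variances, array weights, genes above the median level, the mean of a gene's probe sets, each probe set on its own, arrays centred on medians, quantile normalization, 2 groups only, a linear allele number, other thresholds and leaving out each array. After the data were examined the fit without the block, no offset, an offset of 64 and the linear arrays only were added. So were trended and robust variances on single probe sets, and an exact test over sign changes of the pair differences of the control probe sets. Without the block the difference between the 2 scales enters the residual spread, so calls lost there say nothing about the effect.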

Results

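Gene expression was measured in forelimb cells of mouse embryos at stage E12.5. The cells carried an EGFP reporter at Lbx1, a homeobox gene of migrating limb muscle progenitors, and were flow sorted for green fluorescence. The embryos carried 0, 1 or 2 LacZ alleles of Pitx2, a homeobox transcription factor gene, and are called WT, HET and MUT here. Each genotype had 3 arrays, numbered 1 to 3 in the labels, for 9 arrays in all. The labels do not say whether the arrays of a genotype came from separate embryos or pools. The sex-linked genes, given below, argue against single embryos on the arrays numbered 1 and 2. The p-values measure only the spread between these samples, which may be technical. The median signal lay between 116 and 136 on the 6 arrays deposited as linear signals, numbers 1 and 2. It lay between 6.12 and 6.13 on the 3 arrays deposited as log2 values, number 3. Differences were taken within the numbers, an assumed pairing for numbers 1 and 2, and the number of arrays limits their precision. The annotation used here gave 0 probe sets the symbol Pitx2, so the targeted gene was not analysed here by name and gave no check of the labels.

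The first comparison asked how the sorted cells differ when both Pitx2 alleles are replaced (MUT against WT). The fixed list of limb muscle progenitor regulators was higher in MUT, with 16 of 23 measured members above WT and 7 below. Its median difference was 0.12 on the log2 scale, and the medians of the 3 number-matched pairs were 0.25, 0.12 and 0.19. Pax3, a paired box factor of muscle precursors, was higher by 0.71 ± 0.22 (log2, SD, n = 3 pairs), a 1.64-fold difference. Met, the receptor for the scatter factor HGF that muscle precursors need to leave the somite, was higher by 0.60 ± 0.25 (log2, SD, n = 3 pairs). Pax3 and Met were the 2 members that passed when adjusted over the list alone (limma, adjusted p = 0.0314 for each). Neither passed over all genes (limma, adjusted p = 0.894). Lbx1 itself differed by 0.45 ± 0.13, Eya1, a transcriptional coactivator, by 0.37 and Sim1 by 0.41 (log2), each above WT in all 3 pairs and none past the threshold. The myogenic determination genes stood near WT, with log2 differences of 0.02 for Myf5, -0.08 for Myod1 and 0.01 for Myog, and each changed sign between pairs. A second Myod1 probe set differed by 0.68.

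The list passed camera's test with a preset inter-gene correlation (limma, adjusted p = 0.00642 over 29 lists) and the fry test (limma, adjusted p = 0.0472). It missed the threshold with an estimated correlation (camera in limma, adjusted p = 0.718, although the estimate of 0.00255 lay below the preset 0.01), without the replicate block (0.264), with the linear arrays only (0.0868), without WT replicate 3 (0.0627) and without MUT replicate 3 (0.10). The list median in the last 4 settings was 0.12, 0.09, 0.08 and 0.17. Without the block the scale difference enters the residual spread, so the loss there decides nothing. Centring the arrays on their medians brought the list median to 0.07, and the median of all genes from 0.01 to -0.05. The list still passed there.

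**Figure D1:**
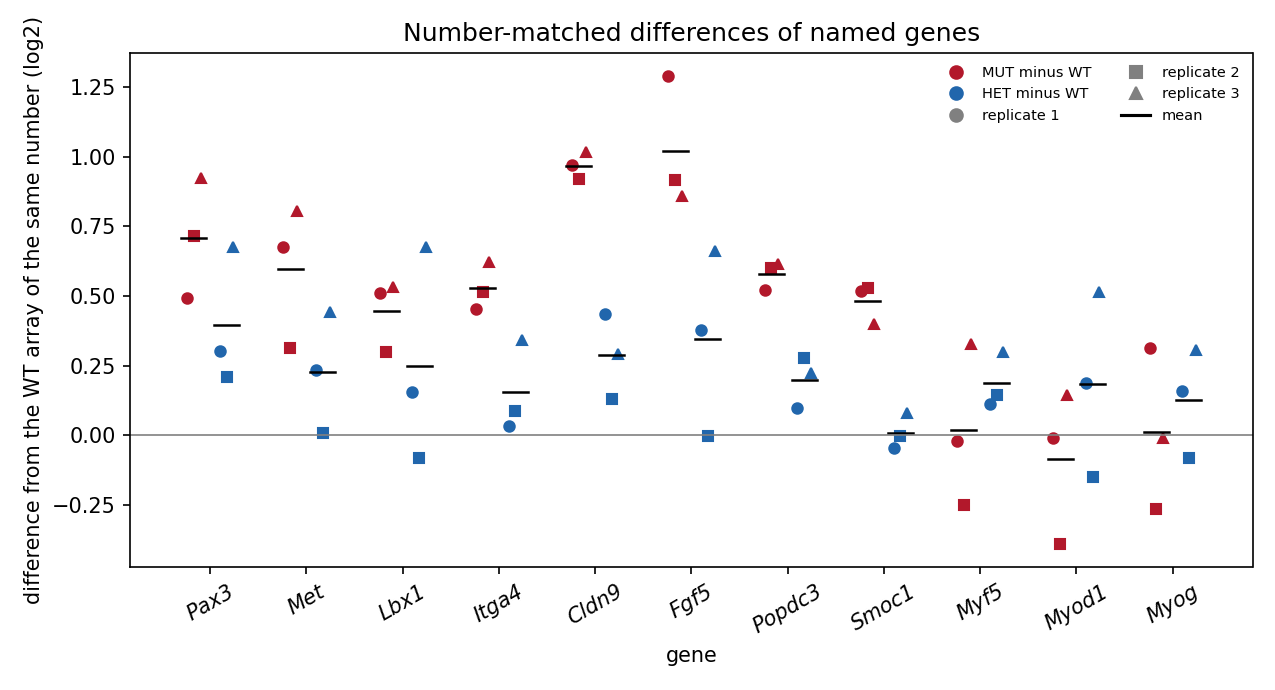
Difference of each MUT (red) and HET (blue) array from the WT array of the same number, in log2 units on the vertical axis, for 11 genes on the horizontal axis. Symbols mark replicates 1 to 3 and black lines their mean. The MUT points of Pax3 lie at 0.49, 0.71 and 0.92, and those of Myog at 0.31, -0.26 and -0.01.

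Other fixed lists also shifted between MUT and WT under the preset correlation, 7 of 29 in all, with 4 higher and 3 lower, and 0 of 29 passed with an estimated correlation. Genes of hypoxia and glycolysis were higher, 23 of 30 members, with a median of 0.13 and pair medians of 0.13, 0.05 and 0.20 (camera in limma, adjusted p = 0.00175, and 0.755 with an estimated correlation). Within that list Ndrg1 differed by 0.38, P4ha2, a collagen prolyl hydroxylase, by 0.35 and Bnip3, a mitophagy receptor, by 0.20 (log2), none past the threshold. G2 and M phase genes were lower, 47 of 51 members, with a median of -0.11 and pair medians of -0.08, -0.25 and -0.02 (camera in limma, adjusted p = 8.55e-09, and 0.755 with an estimated correlation). Among them Hmmr differed by -0.26, Cdc20, an activator of the anaphase-promoting complex, by -0.27 and Nusap1 by -0.26, none past the threshold. S phase genes were lower by a median of -0.05, 32 of 42 members, with pair medians of 0.01, -0.13 and -0.01 (camera in limma, adjusted p = 0.00657, and 0.755 with an estimated correlation). Macrophage and leukocyte genes were lower, 19 of 24 members, with a median of -0.20 and pair medians of -0.20, -0.39 and 0.00 (camera in limma, adjusted p = 0.000499, and 0.755 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, differed by -0.57, the chemokine gene Ccl4 by 0.45, the other way, Mrc1 by -0.41 and Cx3cr1 by -0.58, none past the threshold. Hox and Meis genes, which pattern the body axes, were higher by a median of 0.29, 28 of 36 members, but the pair medians were 0.12, 0.51 and -0.05 (camera in limma, adjusted p = 0.00642, and 0.755 with an estimated correlation). Meis1 differed by 0.44 and Hoxd1 by 0.58, neither past the threshold. Neuron genes were higher by a median of 0.50, 31 of 35 members, but the pair medians were 0.67, 1.25 and -0.16 (camera in limma, adjusted p = 0.00842, and 0.841 with an estimated correlation). The 5′ control probe set of 18S ribosomal RNA was also lower in MUT than in WT, by -4.42, -0.47 and -3.31 in the 3 pairs. The exact permutation test without pairing gave a two-sided p = 0.1, the smallest that 3 against 3 allows. An exact test over sign changes of the pairs gave p = 0.25. The difference between the 3′ and 5′ control probe sets of Actb was larger in MUT in all 3 pairs, by 0.07, 0.05 and 0.14 (log2; exact test over sign changes of the pairs, two-sided, p = 0.25, the smallest that 3 pairs allow). The exact permutation test without pairing gave p = 0.4. For Gapdh the pair differences were 0.00, 0.06 and 0.13 (exact test over sign changes, p = 0.5, and exact permutation test without pairing, p = 0.7).

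The fry test called the progenitor list alone. Other settings also ended calls, some with the median kept and some with it smaller, and list medians are given in parentheses. Hypoxia stood at an adjusted p of 0.10 without MUT replicate 3 (0.09) and 0.107 with the linear arrays only (0.09). Macrophages stood at 0.140 without WT replicate 2 (-0.10) and 0.103 without MUT replicate 1 (-0.11). Hox genes stood at 0.181 without WT replicate 2 (0.12) and 0.646 without MUT replicate 2 (0.10). S phase stood at 0.317 (-0.02) and 0.346 (-0.01) without those same arrays, and at 0.0807 after quantile normalization (-0.04). Neurons stood at 0.116 without WT replicate 2 (0.47), 0.245 without WT replicate 3 (0.41), 0.156 without MUT replicate 1 (0.39) and 0.790 without MUT replicate 2 (0.31). Leaving out 1 array also gave larger medians, up to 1.08 for neurons, 0.47 for Hox genes and -0.33 for macrophages. Without the replicate block 4 lists passed, and hypoxia (0.143) and S phase (0.264) did not, with medians unchanged. The scale difference enters the residual spread there.

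**Figure D2:**
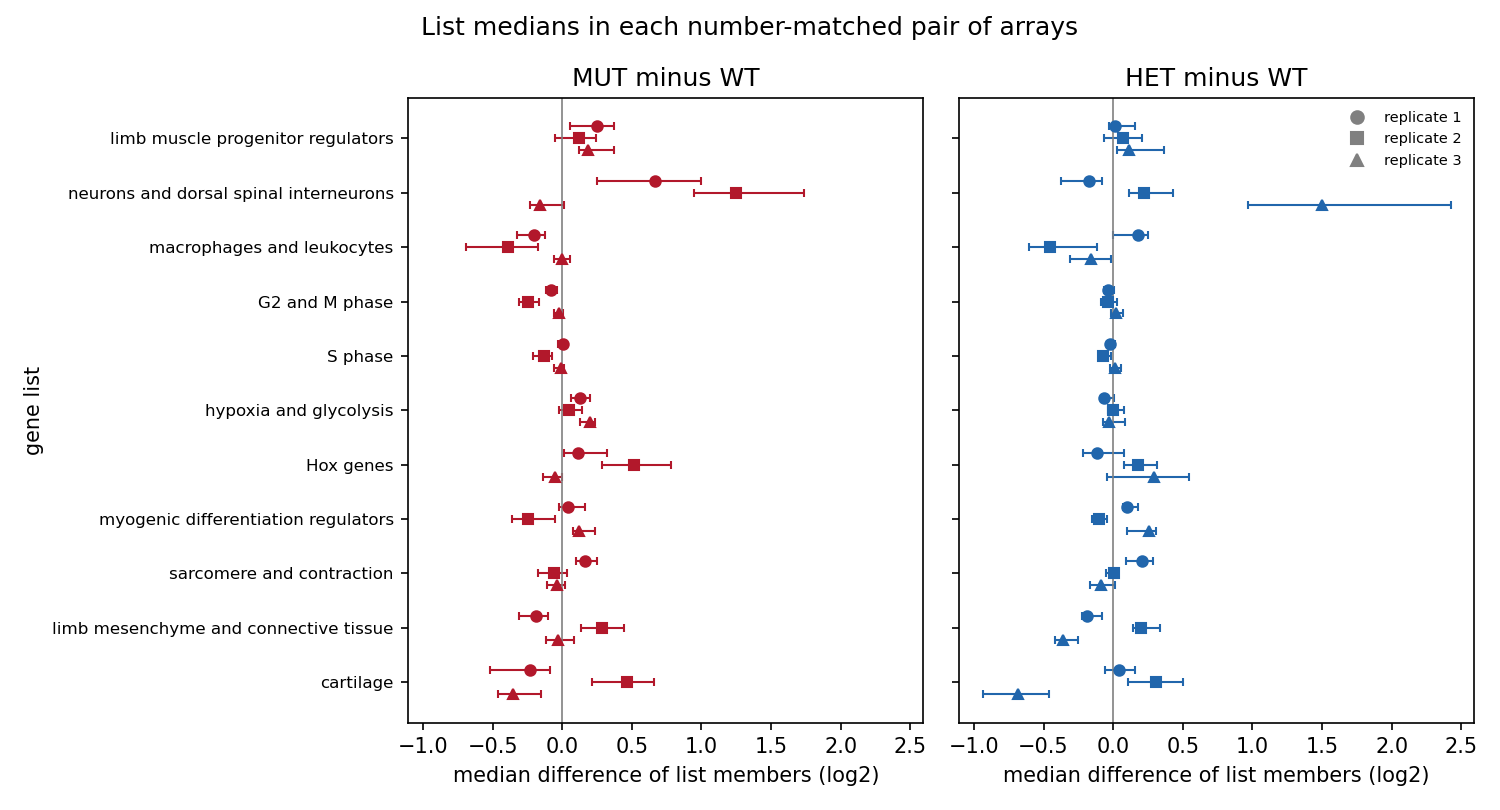
Median log2 difference of the members of 11 gene lists from WT in each number-matched pair of arrays, for MUT (left) and HET (right). Symbols mark replicates 1 to 3, and bars are 95% bootstrap intervals over the list members, which are not independent of each other. The neuron list stands at 1.25 in MUT replicate 2 and at 1.501 in HET replicate 3, against -0.16 in MUT replicate 3 and -0.17 in HET replicate 1.

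Gene by gene, 0 of 18193 genes passed in MUT against WT (limma, smallest adjusted p = 0.894). At an unadjusted p under 0.05 there were 856 genes, 545 higher and 311 lower, where 909.65 are expected by chance, and leaving out 1 array moved that count between 395 and 1476. Centring the arrays on their medians turned that split to 385 higher and 399 lower. The 10 genes with the smallest p were all above WT in each pair. Cldn9, a tight junction claudin, differed by 0.97 ± 0.05 (log2, SD, n = 3 pairs), a 1.96-fold difference. It passed when genes below the median level were left out (limma, adjusted p = 0.0213). Fgf5, a growth factor, differed by 1.02 and Itga4, the alpha 4 integrin, by 0.53, with its 4 other probe sets between 0.28 and 0.48. The others were Popdc3 (0.58), the unconventional myosin Myo16 (0.50), A930005H10Rik (0.64), Pax3, the secreted matrix protein gene Smoc1 (0.48), Tex14 (0.67) and the presynaptic scaffold gene Bsn (0.59). A further Bsn probe set stood at -0.01.

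When each of 45037 probe sets was tested on its own, 1 passed in MUT against WT. Probe set 1450482_a_at, unnamed in the annotation used here and singled out after its values were seen, was 20.9-fold lower in MUT (95% confidence interval 14.9 to 29.3, limma, adjusted p = 0.0250). The MUT signals lay below the median of their arrays and background was not measured, so the size of the fold rests on the offset and the background, and it was -4.05 on the log2 scale with an offset of 64. Its signal was 2419, 3090 and, on the log2 scale, 9.53 in the WT arrays. It was 88.8, 94.3 and, on the log2 scale, 5.72 in the MUT arrays. As a share of the WT array of the same number it was 4.62% ± 2.20 in MUT and 83.0% ± 19.7 in HET (SD, n = 3). A further unnamed probe set, 1424797_a_at, stood at 40.9% ± 10.5 in MUT and 94.8% ± 17.99 in HET (SD, n = 3). It did not pass (limma, adjusted p = 0.937) except with trended and robust variances (limma, adjusted p = 0.0179). The call of 1450482_a_at was lost without the replicate block (limma, adjusted p = 1.00), with no offset (0.233), after quantile normalization (0.0821) and with the linear arrays only (0.671). The log2 difference in those settings was -4.39, -4.54, -4.40 and -4.68, against -4.39 as first fitted. Without the block the difference between the scales enters the residual spread, so the loss there decides nothing. The call was also lost without any 1 array other than WT replicate 3, with adjusted p between 0.126 and 0.517. The difference then stayed between -4.22 and -4.58 (log2).

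The second comparison asked whether a single LacZ allele shifts expression (HET against WT). The progenitor regulators were 0.06 above WT in median, 17 of 23 members, and did not pass (camera in limma, adjusted p = 0.0834). Pax3 differed by 0.40 ± 0.25, Met by 0.23 ± 0.22 and Lbx1 by 0.25 ± 0.39 (log2, SD, n = 3 pairs), none past the threshold. Log2 differences were 0.19 for Myf5, 0.18 for Myod1 and 0.13 for Myog. In this comparison 6 of 29 lists passed under the preset correlation, 3 higher and 3 lower, and 0 of 29 with an estimated correlation. Myogenic differentiation regulators were higher by a median of 0.08, 28 of 39 members, with pair medians of 0.10, -0.10 and 0.26 (camera in limma, adjusted p = 0.0169, and 0.916 with an estimated correlation). Stac3, a component of excitation-contraction coupling, differed by 0.56 and Smyd1, a muscle histone methyltransferase, by 0.28, neither past the threshold, and the other Smyd1 probe sets ranged from -0.25 to 0.62. Erythroid genes were higher by 0.29, 13 of 17 members, with pair medians of -0.11, 0.50 and 0.21 (camera in limma, adjusted p = 0.0114, and 0.916 with an estimated correlation). The embryonic globin gene Hbb-bh1 differed by 0.50 and Sptb by 0.26, neither past the threshold. Epidermis and apical ridge genes were lower by -0.19, 21 of 27 members, with pair medians of -0.11, -0.09 and -0.31 (camera in limma, adjusted p = 0.0169, and 0.916 with an estimated correlation). In that list Grhl3, an epidermal transcription factor, differed by -0.50, and Fgf8, a ridge growth factor, stood higher by 0.51, neither past the threshold. Limb mesenchyme genes were lower by -0.08, 30 of 36 members (camera in limma, adjusted p = 0.0429, and 0.916 with an estimated correlation), with pair medians of -0.18, 0.20 and -0.36. Alx4 differed by -0.40 and Tbx3 by -0.20, neither past the threshold, and the other Tbx3 probe sets ranged from -1.02 to 0.12. Macrophage genes were lower by -0.18, 19 of 24 members, but the pair medians were 0.18, -0.46 and -0.16 (camera in limma, adjusted p = 0.0169, and 0.916 with an estimated correlation). Neuron genes were higher by 0.44, 30 of 35 members (camera in limma, adjusted p = 0.010, and 0.916 with an estimated correlation), with pair medians of -0.17, 0.22 and 1.501. The Actb 3′ to 5′ control difference was larger in HET in all 3 pairs, by 0.02, 0.03 and 0.04 (log2, exact test over sign changes, two-sided, p = 0.25). The exact permutation test without pairing gave p = 0.5. The other controls changed sign between pairs, with -0.001, 0.04 and -0.02 for Gapdh and -0.62, 1.29 and -2.74 for 18S. For 18S the exact test over sign changes gave p = 0.75.

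The fry test called 0 lists. Adjusted p-values in other settings that ended calls are given here with the list median in parentheses. With the linear arrays only, all 6 calls were lost, at 0.757 for myogenic differentiation (0.02), 0.409 for erythroid (0.23), 0.558 for epidermis (-0.14), 0.801 for mesenchyme (0.06), 0.409 for macrophage (-0.17) and 0.945 for neuron genes (0.01). Without HET replicate 3 all 6 were lost too, at 0.463 for myogenic differentiation (0.04), 0.361 for erythroid (0.20), 0.621 for epidermis (-0.13), 0.827 for mesenchyme (0.05), 0.624 for macrophage (-0.13) and 0.410 for neuron genes (-0.17). Without WT replicate 3 the values were 0.786 for myogenic differentiation (0.03), 0.0974 for erythroid (0.38), 0.258 for epidermis (-0.19), 0.890 for mesenchyme (0.00) and 0.234 for neuron genes (0.41). Without WT replicate 1 they were 0.354 for myogenic differentiation (0.05), 0.233 for epidermis (-0.11) and 0.467 for mesenchyme genes (-0.02). Without WT replicate 2 they were 0.304 for erythroid (0.11), 0.701 for macrophage (-0.08) and 0.0659 for neuron genes (0.43). Without HET replicate 2 they were 0.108 for erythroid (0.09), 0.106 for epidermis (-0.19) and 0.261 for macrophage genes (-0.10). Myogenic differentiation stood at 0.196 without HET replicate 1 (0.09) and mesenchyme at 0.0525 without MUT replicate 3 (-0.08). The fit without the replicate block leaves medians unchanged and puts the scale difference into the residual spread. Its adjusted p was 0.392 for myogenic differentiation, 0.202 for mesenchyme and 0.199 for macrophage genes. After centring on medians it was 0.0567 for myogenic differentiation (0.05), 0.0567 for macrophage (-0.21) and 0.0510 for mesenchyme genes (-0.11). It was 0.0576 for mesenchyme genes with no offset (-0.08) and 0.122 for epidermis genes with the mean of probe sets (-0.10).

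Gene by gene, 0 of 18193 genes passed in HET against WT (limma, smallest adjusted p = 1.00), with 578 at an unadjusted p under 0.05, 262 higher and 316 lower. Leaving out 1 array moved that count between 274 and 999. The 10 with the smallest p were 1700086L19Rik (-0.60), the lymphangiogenic factor gene Vegfd (-0.49), Sec14l3 (-0.56), Bsn (0.55), the surfactant protein gene Sftpc (0.63), E330013P04Rik (-0.69), Proser2 (-0.66), Primpol (-0.64), Podn (-0.51) and Ttll13 (0.86), as log2 differences. The 2 other Ttll13 probe sets went the other way, at -0.37 and -0.15, and 1 further probe set each of Vegfd (0.11) and Sec14l3 (0.07) did too. All 45037 probe sets tested on their own gave 0 calls in this comparison.

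The third comparison set MUT against HET, the loss of the second allele. The progenitor regulators were 0.07 higher in MUT in median, 17 of 23 members, and did not pass (camera in limma, adjusted p = 0.139). Pax3 differed by 0.31 ± 0.17 and Met by 0.37 ± 0.07 (log2, SD, n = 3 pairs), neither past the threshold. Under the preset correlation 5 of 29 lists passed, 2 higher and 3 lower, and 0 of 29 with an estimated correlation. Hypoxia and glycolysis genes were higher by 0.14, 28 of 30 members, with pair medians of 0.15, 0.07 and 0.16 (camera in limma, adjusted p = 0.000378, and 0.825 with an estimated correlation). Bnip3 differed by 0.23 and Egln1, an oxygen-sensing prolyl hydroxylase, by 0.19, neither past the threshold, and a second Egln1 probe set stood at -0.01. G2 and M phase genes were lower by -0.09, 49 of 51 members, with pair medians of -0.05, -0.21 and -0.05 (camera in limma, adjusted p = 7.50e-07, and 0.825 with an estimated correlation). Gtse1 differed by -0.31 and Hmmr by -0.19, neither past the threshold. S phase genes were lower by -0.05, 33 of 42 members, and myogenic differentiation regulators by -0.10, 26 of 39 members (camera in limma, adjusted p = 0.0436 for each, and 0.825 with an estimated correlation). Their pair medians were 0.01, -0.11 and -0.04 for S phase and -0.03, -0.18 and -0.02 for myogenic differentiation. Chrng, the fetal acetylcholine receptor subunit, differed by -0.30, the cell surface receptor gene Boc by 0.20, the other way, and Myod1 by -0.27, none past the threshold, and the second Myod1 probe set stood at 0.40. Limb mesenchyme genes were higher by 0.12, 32 of 36 members, with pair medians of -0.05, 0.07 and 0.33 (camera in limma, adjusted p = 0.0436, and 0.825 with an estimated correlation). Irx3 differed by 0.38 and the tendon gene Tnmd by 0.67, neither past the threshold. Neuron genes had pair medians of 0.86, 0.97 and -1.50 in this comparison and did not pass (camera in limma, adjusted p = 0.873). The 18S control probe set was lower in MUT than in HET by -3.81, -1.76 and -0.57 in the 3 pairs. The Actb 3′ to 5′ difference was larger by 0.05, 0.02 and 0.09 (exact test over sign changes, two-sided, p = 0.25 for each). The exact permutation test without pairing gave p = 0.3 for 18S and 0.6 for Actb. For Gapdh the pair differences were -0.003, 0.02 and 0.14 (exact test over sign changes, p = 0.5).

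The fry test called 0 lists. The G2 and M phase and hypoxia calls stood without each array in turn, although the G2 and M phase median went from -0.09 to -0.04 without MUT replicate 2. With the linear arrays only hypoxia stood at 0.0548, with a median of 0.10. The other 3 calls were lost in the settings given here, with list medians in parentheses. Mesenchyme stood at 0.0511 without WT replicate 1 (0.12), 0.941 without HET replicate 3 (0.02), 0.390 without MUT replicate 2 (0.08) and 0.363 without MUT replicate 3 (0.11). S phase stood at 0.0511 without WT replicate 1 (-0.05), 0.218 without HET replicate 3 (-0.03) and 0.711 without MUT replicate 2 (0.00). Myogenic differentiation stood at 0.0565 without WT replicate 1 (-0.10), 0.194 without HET replicate 1 (-0.14), 0.218 without HET replicate 3 (-0.07) and 0.711 without MUT replicate 2 (0.00). Without the replicate block the scale difference entered the residual spread and medians were unchanged. The adjusted p there was 0.307 for myogenic differentiation and 0.324 for S phase genes. After quantile normalization it was 0.0642 for mesenchyme (0.11), 0.0688 for myogenic differentiation (-0.11) and 0.0940 for S phase genes (-0.04). With the linear arrays only it was 0.816 (0.05), 0.0675 (-0.09) and 0.168 (-0.04) for the same lists, and with no offset myogenic differentiation stood at 0.0515 (-0.11).

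Gene by gene, 0 of 18193 genes passed in MUT against HET (limma, smallest adjusted p = 0.944), with 802 at an unadjusted p under 0.05, 547 higher and 255 lower. Leaving out 1 array moved that count between 382 and 1291. The 10 with the smallest p were Cldn9 (0.68), the prostaglandin-degrading enzyme gene Hpgd (0.73), Vegfd (0.52), E430018J23Rik (0.71), Smoc1 (0.47), Proser2 (0.73), the zinc finger factor gene Gata6 (0.73), Frmd4b (-0.46), 4933432I09Rik (0.61) and Pcp2 (0.52), as log2 differences. The 2 other Pcp2 probe sets stood at -0.06. Of 45037 probe sets tested on their own, 1450482_a_at alone passed, 17.1-fold lower in MUT than in HET (95% confidence interval 12.2 to 23.9, limma, adjusted p = 0.0377). That call was lost in the same settings as in MUT against WT, where the log2 difference stayed between -3.94 and -4.29.

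The last tests asked whether HET lay away from the midpoint of WT and MUT and whether any genotype differed. In both, 0 of 18193 genes passed (limma, smallest adjusted p = 1.00 and 0.962), with 609 and 597 genes at an unadjusted p under 0.05. Without 1 array those counts lay between 286 and 1111 and between 302 and 1068. The 5 genes with the smallest p against the midpoint were Vegfd (-0.50), 1700086L19Rik (-0.46), Proser2 (-0.69), Hpgd (-0.47) and 4933432I09Rik (-0.53), each below the midpoint in all 3 numbers. For any genotype difference they were Cldn9, Popdc3, Hpgd, 1700086L19Rik and Vegfd. Tested on their own, 1 probe set, 1450482_a_at, passed for any genotype difference and 0 passed against the midpoint.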

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

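The settings without the block, with no offset or an offset of 64, with the linear arrays only, and with trended and robust variances on single probe sets were chosen after the data were examined. The count of 0 genes held in all 5 tests with array weights, trended and robust variances, the mean of probe sets, either other scaling, either other offset, the linear arrays only, an adjusted p under 0.1, and without each array in turn (0 to 0). It held in the 3 pairwise comparisons with the 2 groups only and in MUT against WT with the linear allele number. Without the replicate block it was also 0, but there the scale difference enters the residual spread, so that 0 decides nothing. The genes at an unadjusted p under 0.05 then numbered 110 in MUT against WT, 101 in HET against WT and 116 in MUT against HET. The exception among genes was Cldn9, the 1 gene past the threshold in MUT against WT when genes below the median level were left out. There fewer genes were tested, and the eBayes prior was estimated from those genes alone, so the p-values changed too. Testing each probe set on its own gave 1 call in MUT against WT, 1 in MUT against HET and 1 in the F test. Trended and robust variances on probe sets gave 2, 2 and 2, and 1 against the midpoint. Unadjusted p under 0.05 gave 856 genes in MUT against WT, 578 in HET against WT, 802 in MUT against HET, 609 against the midpoint and 597 in the F test, by construction. Without 1 array these unadjusted counts ranged from 395 to 1476, 274 to 999, 382 to 1291, 286 to 1111 and 302 to 1068.

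Counts of gene lists moved more. In MUT against WT 7 lists passed, against 4 without the replicate block, 1 with fry, 0 with an estimated correlation and 5 to 7 without 1 array. In HET against WT 6 passed, against 3 after centring on medians, 1 with the linear arrays only (immediate early genes, none of the 6), 9 after quantile normalization, 0 with fry, 0 with an estimated correlation and 1 to 8 without 1 array. In MUT against HET 5 passed, against 2 after quantile normalization, 0 with fry, 0 with an estimated correlation and 2 to 9 without 1 array. The estimated correlation lay between -0.05 and 0.50, above the preset 0.01 for most lists but below it for the progenitor list. For that list in MUT against WT the unadjusted p still rose from 0.00111 to 0.0248 (camera in limma). A higher correlation therefore cannot account for the loss of that call. With an estimated correlation camera also uses the 4 residual degrees of freedom, not the number of genes, which raises p at the same correlation. The absence of calls there thus reflects few arrays as well as the correlation. The cause of these moves was not otherwise tested. Over all settings, those above included, 111 list calls were lost, 4 of them with the direction turned, and 61 were gained, 5 of them with the direction turned.

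Reversed directions were few. With the mean of probe sets Tiam1 stood at -0.0148 and Synpo2 at -0.0709 in MUT against HET, and with an offset of 64 Usp53 stood at -0.23 in HET against WT, none of them called. With the linear arrays only the direction of the camera test turned for mesenchyme (adjusted p = 0.801) and neurons (0.945) in HET against WT and for neurons in MUT against HET (4.44e-12). The neuron medians kept their sign there, at 0.01 and 0.90. Without 1 array the adjusted p of lists whose test direction turned ranged from 1.36e-08 to 0.890 for mesenchyme and from 7.25e-07 to 0.410 for neurons in HET against WT. It ranged from 2.72e-06 to 0.875 for neurons in MUT against HET, from 0.0115 to 0.892 for mesenchyme and from 0.00581 to 0.968 for myogenic differentiation in MUT against WT. The test turned for neurons without HET replicate 3 or MUT replicate 3, for mesenchyme without HET replicate 3 or WT replicate 2, and for myogenic differentiation without WT replicate 2; the cause was not tested. In MUT against HET the neuron median was above 0 in those settings (0.77 and 0.64), against 0.06 as first fitted. It was -0.33 without HET replicate 1 and -0.35 without MUT replicate 2. The list passed as lower in both (camera in limma, adjusted p = 0.0420 and 0.0334). The Pitx2 settings were not run, since no probe set carried that symbol. Precision was lower for dim genes, with a median 95% half-width of 0.66 log2 against 0.26 for brighter ones; background itself was not measured.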

Other observations

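The 3 tests of the neuron list and the sarcomere test were chosen after the values they use had been seen. The covariate test of the progenitor list replaced an earlier test on replicate 3 alone, whose result had been seen (median 0.188), because 1 pair of arrays excludes nothing. Its need to hold with an estimated correlation was added after its first result had been seen. The Hox and immediate early values with that covariate were chosen after they had been seen. The other tests were written before their own results.

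Lists not described so far did not pass in any comparison under the preset correlation as first fitted. Some passed in other settings, such as cartilage in HET against WT without WT replicate 2 (adjusted p = 6.03e-07) and liver in MUT against WT after centring on medians (0.0314). The smallest adjusted p among them was 0.0637, for cartilage in HET against WT (camera in limma). In MUT against WT the median log2 differences were 0.07 for sarcomere and contraction, 0.00 for actin cytoskeleton and motility, 0.06 for adhesion receptors, -0.14 for cartilage, 0.10 for Schwann cell precursors, -0.06 for endothelium and 0.22 for pericytes. They were 0.00 for the Wnt, -0.02 for the Notch, 0.04 for the BMP and 0.03 for the FGF pathway, 0.00 for immediate early genes, 0.04 for p53 targets, -0.02 for interferon response, 0.38 for liver, 0.04 for ribosomal proteins and -0.02 for the neighbourhood of Pitx2. Liver medians were 0.13, 0.68 and 0.00 in the 3 pairs of MUT and WT, with the largest in pair 2. Cartilage medians were -0.23, 0.46 and -0.35 in the 3 pairs of MUT and WT, and 0.04, 0.31 and -0.69 in those of HET and WT. With the mean of the neuron list as a covariate the Hox median in MUT against WT was 0.15, against 0.29 without it (camera in limma, adjusted p = 0.0461, and 0.852 with an estimated correlation). The immediate early list passed with that covariate at 0.00474, and not with an estimated correlation (0.759). Itga4 passed in MUT against WT when adjusted over the Schwann cell precursor list alone (limma, adjusted p = 0.0204). The adhesion receptor list also holds it, and there 0 members passed in this way (limma, smallest adjusted p = 0.0708). The median differed in sign from the camera test for 4, 3 and 4 lists in MUT against WT, HET against WT and MUT against HET, none of them a called list.

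Sex-linked genes differed by 0.04, -0.03 and 1.15 (median log2) in the pairs of MUT and WT, and by -0.15, -0.12 and 1.02 in those of HET and WT. On the log2 arrays the Y-linked gene Kdm5d stood at 5.87 in WT, 7.35 in HET and 7.73 in MUT, and Xist at 10.8, 10.8 and 10.2. On the linear arrays Xist lay between 3595 and 5597 and Eif2s3y between 602 and 780. The Y-linked Kdm5d value of the log2 WT array lay below that array's median of 6.13. Xist and the Y-linked Eif2s3y were both above the median on every linear array. Xist marks female and Y-linked genes male cells, so these values argue against a single embryo as the source of a linear array. On the log2 arrays Eif2s3y stood at 6.60 in WT, 7.92 in HET and 8.15 in MUT, and Uty at 5.63, 6.35 and 6.39. Differences from WT in pair 3 may therefore carry a difference in sex make-up, which was not tested.

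Neuron genes were high on particular arrays of both genotypes. Against WT replicate 3, 26 of 35 list members were higher by over 0.5 log2 in HET replicate 3, and at most 10 were in the other HET arrays. The pan-neuronal tubulin gene Tubb3 stood at 10.9 there against 7.89 in WT replicate 3 (log2), and Stmn2 at 813 in MUT replicate 2 against 53.6 in WT replicate 2 (linear signal). This is consistent with neurons or their RNA in some sorted samples. Dorsal spinal interneurons express Lbx1, so the sort would keep them and only the dissection would remove them. Of the 35 genes, 6 lay above the median level in WT. Against WT replicate 2, MUT replicate 2 also stood higher in the liver (0.68), erythroid (0.62) and Hox lists (0.51), and lower in macrophage genes (-0.39). The rise on that array was therefore not particular to neuron genes. The offset and the mixed scales cannot account for HET replicate 3, where the list median was 1.501 (0.97 to 2.43, 95% bootstrap interval over members) between arrays of 1 scale that carry no offset. Loss of both alleles cannot account for the rise in HET replicate 3, which carries 1 LacZ allele. For the MUT arrays it stays open, since the median of -0.16 in MUT replicate 3 (-0.22 to 0.00) comes from 1 pair.

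The higher progenitor genes in MUT were weighed against 3 explanations. With the mean of the neuron list as a covariate their median was 0.14 (0.00138 to 0.328, 95% bootstrap interval) and the list passed (camera in limma, adjusted p = 0.00474), but not with an estimated correlation (0.523). The lower bound lies barely above 0 and the members are not independent, so neurons stay open as a cause. The lowest median over no offset, an offset of 64, both scalings and each scale alone was 0.0661, which argues against the offset, the scaling or 1 scale as the whole cause. A lower share of differentiated myogenic cells stays open, since the sarcomere list stood at 0.0691 (-0.03 to 0.13). RNA quality was not tested as a cause, although the 18S control was lower and the Actb 3′ to 5′ difference larger in MUT in all 3 pairs. The Gapdh difference was not larger in each pair. The sex make-up of WT replicate 3 was not tested either. A genotype effect on the progenitor genes or on their share of the sorted cells stays a hypothesis, since it was found and tested on the same arrays.

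The lower G2 and M phase genes in MUT were largest in replicate 2. Without MUT replicate 2 the median was -0.0716 (-0.09 to -0.02, 95% bootstrap interval over members), so that array did not carry all of the measured shift. After quantile normalization it was -0.10 (-0.12 to -0.08), so that scaling did not remove the shift. The members are not independent, with an estimated correlation of 0.30. Their intervals hold no spread between arrays, so they do not show that the shift exceeds it. In replicate 3 the median was -0.02 (-0.06 to 0.01). Differences in cell handling or embryo stage were not tested, and a genotype effect stays open.

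Splits of the arrays, with the third genotype and the block kept, were too few for a share under 0.05 in the pairwise comparisons. Each count of splits given here includes the real one. The gene counts of 0 decide nothing here, since every split gives at least 0 (10 of 10 in MUT against WT, in HET against WT and in MUT against HET, with 0 the highest of the others). For lists, 4 of 10 splits gave at least the real 7 in MUT against WT, with 10 the highest of the others. In HET against WT 6 of 10 gave at least the real 6, with 10 the highest other, and in MUT against HET 6 of 10 gave at least the real 5, with 15 the highest other. That split called several times the real count, which may come from a structure of the samples or from a preset correlation below most estimates, and neither was tested. Among the 4 splits that part all 3 pairs the highest others were 6, 8 and 8 lists; the remaining splits place both arrays of a number in 1 group. The same holds for the midpoint and the F test, where 100 of 100 splits, the real one included, gave at least the real 0 by construction. The highest others were 4 and 0.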
